A study of Mus musculus with 4 samples.

How the data were processed

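RNA of 4 cultures of mouse embryonic lung explants was measured, 2 without and 2 with dexamethasone at 100 nM for 24 hours. Per the labels' protocols, the RNA was extracted with Trizol, cleaned on a micro column, amplified, labelled with biotin and hybridised to Illumina bead arrays. The submitters' processing notes name GenomeStudio, without a version. The table deposited by the authors holds, per the file headers, a mean bead intensity on a linear scale for each probe and array, with the standard error over its beads, the number of beads and a detection p-value. These intensities were not normalized between arrays, as far as their values show: their medians ran from 105.5 to 114.3. A second table, deposited by the authors as processed intensities, is also on a linear scale. Within each array it followed the order of the first table (Spearman correlation of 1.00 over all probes), with medians from 110.7 to 113.0. How the authors normalized it is not given in the sources used here, and it was used only as an alternative.

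Of 45281 probes, 36923 were named through the RefSeq gene table by gene identifier, accession, symbol or older symbol, and 8358 kept the symbol of the file, giving 28860 names. No coordinates are printed, since the build of the probe positions is not given in the sources used here.

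From the intensities, neqc in limma 3.58.1 (R 4.3.3) estimated the background from the detection p-values, added an offset of 16, quantile-normalized the arrays and took log2. Probes with a detection p under 0.05 on at least 2 of the 4 arrays were kept, 20168 in all. Each gene was represented by its kept probe with the highest mean over the 4 arrays, which left 13714 genes. Some genes had another kept probe that differed by over 1.5 times or in sign. Beside those given with the results, these probes showed, in log2 units, 0.88 for Hp, -1.36 for Ret, -0.026 for Sox9, 0.040 for Id2, 0.57 for Scgb3a2, -0.98 for Acta2, 1.42 for Slc10a6, 0.62 for Osbpl6 and -0.036 for Pecam1, each the probe furthest from the one used. Dexamethasone was compared with control by lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The fit leaves 2 residual degrees of freedom, and eBayes shares the spread across genes. Values are log2 intensities as mean ± SD with n = 2, and changes are log2 differences ± the SE of the fit. With 2 arrays against 2, 33.3% of all splits separate any 4 values, so that groups that do not overlap carry little weight alone. A gene not detected on either array of a group has a bound in place of a fold. A gene detected on 1 array of a group keeps its fold, which then rests partly on signal near background.

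The experiment number in the labels marks arrays of a shared experiment, so the numbers were taken to pair the samples. As a check, the deviations of same-numbered arrays from their group means correlated at 0.31 across genes, and the second principal component (21.5% of the variance) separated the experiments while the first (65.8%) separated the groups. The main fit left this pairing out, so genes said to pass or not to pass without mention of the block were tested unpaired. The fit with the experiment as an additive block leaves 1 residual degree of freedom and is given beside results whose call it changes.

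The 27 gene lists of pathways and cell types, markers of cell types beside the epithelium included, were fixed before the data were examined, as were the groups, the main tests and the alternatives. Each list was tested with camera, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, with members tested one by one over all genes and adjusted over the list alone. None of the 12 lists called by camera was called with an estimated correlation. That setting rests on the 2 residual degrees of freedom and has little power. The smooth muscle estimate, -0.060, was below the preset, yet camera's unadjusted p went from 0.00044 to 0.065. A list that it did not call is therefore not shown to be unshifted. The estimate was 0.76 for neuron and Schwann cell genes, 0.62 for cell cycle genes and 0.54 for both alveolar type 2 and alveolar type 1 genes. It was 0.48 for hypoxia response and 0.39 for airway secretory genes. The preset can make p too small for such lists. The rule for named genes took the 10 largest rises and the 10 largest falls among genes that passed, had the same sign in both experiments and did not overlap between groups, leaving out predicted genes. It also took up to 4 members with the smallest p from each list, and a set of glucocorticoid and lung genes named whatever their values.

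The scripts' steps were tested on simulated data for the comparison of dexamethasone with control. In 20 data sets of 13714 genes, drawn from the real means and spreads with 200 changed genes, the fit without the block recovered 31.9% of the genes changed by 1 log2 unit, 98.6% of those changed by 2 and 0.10% of those changed by 0.5, and 3.26% of its calls were false. With the block these were 57.3%, 99.1%, 1.10% and 6.98%. The simulated genes were independent, with spreads drawn from the blocked fit and an experiment effect of the same variance for all genes. The rates hold for these settings and need not hold for the real comparison. Camera called 100% of lists of 20 genes shifted by 0.5 and 0% of unshifted lists of independent genes.

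Alternatives covered 4 other normalizations (quantile normalization without background correction, normexp with an offset of 50, the authors' processed values, and a median shift in place of quantile normalization), no filter and a strict one (detection p under 0.01 on all 4 arrays), other uses of a gene's probes, the replicate block, eBayes with an intensity trend and robust estimation, other thresholds and set tests, and leaving out each array in turn. Where an array is left out, the arm with 1 array is assumed to vary like the other. Such a fit also leaves out the pairing, so differences between the experiments enter its changes, list medians and counts. With the intensity trend, camera used the trend without robust estimation. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 in Python 3.11.15.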

Results

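Lungs of mouse embryos at embryonic day 14 were kept as explants on membranes in serum-containing medium. One group received dexamethasone, a synthetic glucocorticoid that activates the glucocorticoid receptor, at 100 nM for 24 hours, and the other received none. The study's title names the effect of dexamethasone on the cultured lung as its question. Transcript levels were measured on 4 single-colour Illumina bead arrays of 45281 probes, 2 control and 2 dexamethasone, with 1 array of each group from each of 2 numbered experiments that the labels call biological replicates. Between 42.8% and 43.9% of the probes were detected on each array, with a median of 41 to 42 beads per probe. The bead standard error had a median of 4.0% to 4.9% of the intensity of a detected probe. The number of arrays, 2 per group, limits the precision of every value below.

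Dexamethasone raised more genes than it lowered, and the genes with the largest rises included enzymes, a sodium channel and surfactant genes. In the main fit, which leaves out the pairing by experiment, 140 of 13714 genes tested rose and 31 fell, 171 in all. Hsd11b1, the enzyme that regenerates active glucocorticoid from its inactive form, rose 24.7-fold, from 6.31 ± 0.75 to 10.94 ± 0.45 on the log2 intensity scale (SD, n = 2). Napsa, an aspartic protease that processes surfactant protein precursors, rose 18.2-fold, from 6.47 ± 1.06 to 10.66 ± 0.65. Within experiments 1 and 2 it stood 4.48 and 3.90 log2 units higher. On leaving out 1 array, which breaks the pairing by experiment, it rose by 10.9-fold to 30.6-fold. Prss35, a serine protease-like gene, fell the most of the named lower genes that passed, from 7.77 ± 0.33 to 5.88 ± 0.07. The median change of the lower genes that passed was -1.24 log2 units against 1.65 for the higher genes. Background limits both sizes, so these medians may not compare like with like. Of the changed genes 21 were not detected on either control array, and 4 were not detected on either dexamethasone array. In limma's test with Benjamini-Hochberg adjustment, the adjusted p was 0.018 for Hsd11b1, 0.047 for Napsa and 0.031 for Prss35. Of the 171 changed genes, 166 changed over 2-fold.

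With the experiment as a replicate block, 826 genes passed, 520 higher and 306 lower, and they included all 171. The share of higher genes was 81.9% in the fit without the block, 63.0% with it, and 64.3%, 66.1% and 67.0% under quantile normalization without background correction, normexp with quantile normalization, and a median shift of the arrays. It was 78.4% in the authors' processed values, 68.2% with the strict filter, 60.7% with an intensity trend and robust variance and 92.5% without a filter. Without control replicate 1, control replicate 2, dexamethasone replicate 1 or dexamethasone replicate 2, the count was 8, 8, 95 or 9 genes, of which 8, 8, 63 and 8 were among the 171.

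The 10 named genes with the largest rises were Tmem213, Hsd11b1, Xdh, Ass1, Aspg, Napsa, Fmo1, Scnn1a, Sult1a1 and Sftpa1. Tmem213, a transmembrane protein gene, rose by 4.92 ± 0.36 log2 units (SE), and Ass1, the argininosuccinate synthase of the urea cycle, by 4.41 ± 0.26. Fmo1, a flavin-containing monooxygenase, rose by 4.11 ± 0.17, and its other kept probe showed 2.66. The 4 kept probes of Hsd11b1 ranged from 1.01 to 4.62. Tmem213 was detected on 1 control array. Xdh, the xanthine dehydrogenase of purine breakdown, Aspg, an asparaginase, Scnn1a, the alpha subunit of the epithelial sodium channel, and Sult1a1, a sulfotransferase, were not detected on either control array. They were at least 19.6-fold, 14.6-fold, 14.5-fold and 9.85-fold higher with dexamethasone, where the bound sets the dexamethasone mean against the lowest signal of a detected probe on the control arrays. Adjusted p ran from 0.0027 for Aspg and Scnn1a to 0.047 for Napsa. Sizes of dim genes were smaller in the authors' processed values. There Scnn1a came to 2.18 and Sult1a1 to 1.88 log2 units, and both still passed. These are differences from control signal that was not detected, not folds. The bounds above hold on the neqc scale only.

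Among named genes that passed, the 10 with the largest falls were Prss35, Btbd11, Rragb, Otof, Hs6st2, Epha5, Gal, St8sia2, Adam12 and Dgkk. Hs6st2, a heparan sulfate 6-O-sulfotransferase, fell by 1.58 ± 0.13 log2 units (SE), with -0.89 at its other kept probe, and St8sia2, a polysialyltransferase, fell by 1.47 ± 0.15. Epha5, an ephrin receptor, fell by 1.54 ± 0.15, Gal, the neuropeptide galanin, by 1.48 ± 0.19, and Adam12, a metalloprotease of mesenchymal cells, by 1.39 ± 0.18. Otof and Dgkk were not detected on either dexamethasone array and were at least 2.34-fold and 2.03-fold lower. Rragb and Gal were each detected on 1 dexamethasone array. Adjusted p of these 10 genes ran from 0.017 for Hs6st2 to 0.045 for Gal and Adam12. In the authors' processed values their changes were smaller, from -0.96 for Prss35 to -0.44 for Dgkk, and all 10 passed. For Otof and Dgkk these are differences from signal that was not detected, and their bounds hold on the neqc scale only.

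**Figure D1:**
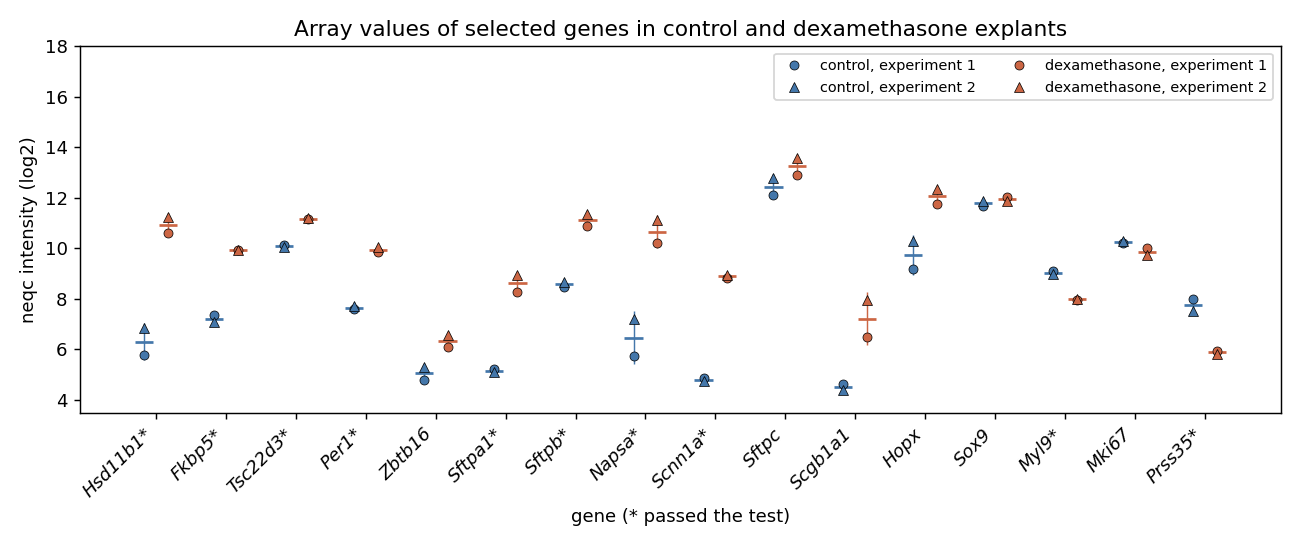
Normalized log2 intensities of 16 genes on the 4 arrays, with control arrays in blue and dexamethasone arrays in orange, circles for experiment 1 and triangles for experiment 2, a horizontal line at each mean and a vertical bar of 1 SD; an asterisk marks genes that passed the test. Scnn1a stands at 4.80 in control and 8.90 with dexamethasone, while Sox9 stands at 11.78 and 11.97 and did not pass.

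Known glucocorticoid targets shifted upward as a list, with a camera adjusted p of 1.1e-18 and an adjusted p of 0.50 with an estimated correlation. Here and below, the setting with an estimated correlation had little power, since it rests on 2 residual degrees of freedom. The preset of 0.01 can in turn make p too small where members correlate, and the estimate was 0.25 for this list. Of 26 measured members of this list, 11 rose, none fell and 15 did not pass. Fkbp5, a co-chaperone of the receptor, rose 6.58-fold from 7.21 ± 0.19 to 9.93 ± 0.02 (SD, n = 2), and Per1, a circadian clock gene, rose 4.90-fold from 7.66 ± 0.06 to 9.95 ± 0.13. Klf9, a transcription factor, rose by 1.78 ± 0.18 and Tsc22d3, which encodes the anti-inflammatory protein GILZ, by 1.08 ± 0.13 log2 units (SE). Zbtb16 stood 1.28 ± 0.24 higher without passing (adjusted p = 0.082) and passed with the replicate block (adjusted p = 0.012). It was detected on 1 control array. All 26 members had positive values, with a median of 1.04, and 20 passed when adjusted over the list alone. With the replicate block 16 members passed over all genes. The transcript of the receptor itself, Nr3c1, was not tested, since its probes did not meet the detection filter.

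Genes of alveolar type 2 cells, the surfactant-producing cells of the alveolus, shifted upward as a list, with a camera adjusted p of 8.2e-11 and an adjusted p of 0.54 with an estimated correlation. Of 21 measured members 7 rose and none fell: Sftpa1, Sftpb, Slc34a2, Ctsh, Napsa, Cxcl15 and Lamp3. Surfactant protein gene Sftpa1 rose 10.9-fold from 5.16 ± 0.08 to 8.61 ± 0.47, and Sftpb 5.87-fold from 8.58 ± 0.13 to 11.14 ± 0.33 (SD, n = 2). Slc34a2, a phosphate transporter, rose by 3.09 ± 0.26 log2 units (SE). Sftpc stood at 12.45 ± 0.49 in control and 13.25 ± 0.46 with dexamethasone and did not pass (adjusted p = 0.26), while it passed with the replicate block (adjusted p = 0.032). Sftpd, 7.98-fold higher (4.61-fold to 13.8-fold on leaving out 1 array), and the surfactant lipid transporter Abca3, 1.27 ± 0.19 higher, likewise passed with the block (adjusted p = 0.0024 and 0.012) but not without it (adjusted p = 0.10 and 0.060). Sftpd was detected on 1 control array and stood 2.85 and 3.15 log2 units higher within experiments 1 and 2. With the block 13 members passed, and 15 passed without it when adjusted over the list alone. The list had a median of 0.89, or 0.84 with undetected members at their bounds.

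Genes of alveolar type 1 cells, the thin gas-exchange cells, also shifted upward as a list, with a camera adjusted p of 1.5e-09 and an adjusted p of 0.54 with an estimated correlation. Of 25 measured members 1, the basement membrane collagen Col4a3, rose on its own test (2.06 ± 0.24 log2 units, adjusted p = 0.035). Hopx stood 2.33 ± 0.41, Ager 1.28 ± 0.37 and Pdpn 0.47 ± 0.20 log2 units higher without passing (adjusted p = 0.070, 0.17 and 0.28), and the other kept probe of Hopx showed 1.16. Aqp5, a water channel of these cells, stood at 4.90 ± 0.48 and 4.94 ± 0.35 (SD, n = 2). It was detected on 1 array of each group, so little can be read from these values. Col4a3 was detected on 1 control array. With the replicate block 13 members passed, Hopx (adjusted p = 0.0052) and Ager (adjusted p = 0.030) among them. Adjusted over the list alone, 16 members were higher and 1 lower. The list's median was 0.97.

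Airway secretory genes shifted upward as a list, with a camera adjusted p of 5.7e-05 and an adjusted p of 0.54 with an estimated correlation. Of 11 measured members 2 rose: Hp, the hemoglobin-binding protein haptoglobin, by 1.39 and Cbr2, a carbonyl reductase, by 2.64 log2 units (adjusted p = 0.029 and 0.049). The club cell gene Scgb1a1 was not detected on either control array and was at least 4.52-fold higher with dexamethasone without passing (adjusted p = 0.071; 0.025 with the block), with dexamethasone replicates 1 and 2 apart at 6.48 and 7.97. Scgb3a2 stood 0.94 ± 0.17 higher (adjusted p = 0.076; 0.025 with the block), and the airway transcription factor Sox2 stood at 5.95 ± 0.43 and 5.81 ± 0.84 (SD, n = 2). With the block 6 members passed, and 6 passed without it when adjusted over the list alone. The list's median was 0.98, or 0.27 without the detection filter. Foxj1, the master regulator of ciliated cells, stood 0.25 ± 0.19 higher (adjusted p = 0.53), and none of 13 ciliated and neuroendocrine genes passed (list median 0.25, camera adjusted p = 0.31).

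Distal tip progenitor genes shifted slightly upward, with a median of 0.28, a camera adjusted p of 0.010 and an adjusted p of 0.54 with an estimated correlation. Of 18 measured members 1 rose, Bex4 (1.15 log2 units, adjusted p = 0.040), as 1 did when adjusted over the list alone and 2 with the block. The tip transcription factor Sox9 stood at 11.78 ± 0.16 in control and 11.97 ± 0.11 with dexamethasone (SD, n = 2), and Id2 and Etv5 stood 0.45 ± 0.26 and 0.42 ± 0.17 higher, none of them passing. Bmp4 stood 0.44 ± 0.15 and Shh 0.24 ± 0.18 higher (adjusted p = 0.21 and 0.53). Spry2 was not tested. The list's camera adjusted p was 0.11 without dexamethasone replicate 1. Among 21 branching signal genes none passed (median 0.04, camera adjusted p = 0.20), though Fgf10, the mesenchymal growth factor that drives bud outgrowth, stood 0.91 ± 0.20 higher and passed with the block (adjusted p = 0.11 and 0.032), and 3 members passed with it.

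Smooth muscle genes shifted downward as a list, with a camera adjusted p of 0.0020 and an adjusted p of 0.50 with an estimated correlation. Of 14 measured members 1 fell, the myosin light chain Myl9 (-1.07 log2 units, adjusted p = 0.044), and 6 were lower when adjusted over the list alone. Tpm2 and Myh11 stood at -0.78 and -0.92 without passing (adjusted p = 0.065 and 0.076) and passed with the replicate block (0.034 and 0.042), as 4 members did. Acta2, smooth muscle actin, went from 13.26 ± 0.06 to 12.69 ± 0.18 (SD, n = 2; adjusted p = 0.14). The list's median was -0.53. It was -0.32 under quantile normalization without background correction, -0.27 in the authors' processed values and -0.27 without the detection filter.

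Cell cycle genes were lower as a list while no member passed on its own, with a camera adjusted p of 2.8e-07 and an adjusted p of 0.54 with an estimated correlation. Of 27 measured members 1 had a positive value, and the median was -0.44. Mki67, the proliferation marker, stood at 10.27 ± 0.06 in control and 9.87 ± 0.18 with dexamethasone (SD, n = 2; adjusted p = 0.25). Pcna, the replication clamp, stood at -0.72 ± 0.15 log2 units (adjusted p = 0.10) and was the only member to pass with the block (adjusted p = 0.046). None passed when adjusted over the list alone. The median was -0.67 without dexamethasone replicate 1, -0.29 without dexamethasone replicate 2 and -0.29 in the authors' processed values.

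Of 31 inflammatory mediator genes 14 were measured, and Il6, Il1b, Tnf and Ptgs2 were among those that were not. The 14 measured members were lower as a list, with a median of -0.47. Camera adjusted p was 0.011, and 0.50 with an estimated correlation. None passed on its own, and 6 were lower when adjusted over the list alone. The chemokines Ccl4 and Cxcl12 stood at -1.24 and -1.03 log2 units (adjusted p = 0.081 and 0.083) and passed with the block (0.044 and 0.019), as 4 members did, while the other kept probe of Ccl4 showed -0.52. The list's median was -0.25 without control replicate 1 and between -0.17 and -0.29 without the filter, without background correction, with normexp and in the authors' processed values.

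Genes of ion and water transport and of fatty acid and phospholipid synthesis shifted upward as lists. Camera adjusted p was 0.0039 for transport and 0.012 for lipid synthesis, and with an estimated correlation both had an adjusted p of 0.50. In the first list 2 of 19 measured members rose: Scnn1a and Atp1b1, a subunit of the sodium pump, by 1.57 ± 0.17 log2 units (SE, adjusted p = 0.032). In the second, 2 of 23 rose: Lpin1, a phosphatidate phosphatase, by 2.09 ± 0.16, and Acss2, an acetyl-CoA synthetase, by 1.58 (adjusted p = 0.015 and 0.035). Nedd4l, a ubiquitin ligase that acts on the sodium channel, stood 1.21 higher and the chloride channel Clcn2 stood at -0.85 log2 units; neither passed over all genes without the block (adjusted p = 0.059 and 0.061), and both passed with it (0.014 and 0.029). With it, 5 transport genes were higher and 1 was lower. Adjusted over the list alone and without the block, 6 transport genes were higher and 3 lower, and 5 lipid synthesis genes were higher. The medians were 0.32 and 0.22, and without dexamethasone replicate 1 the lipid list's adjusted p was 0.072.

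Hypoxia response genes had a median of 0.27 over 20 measured members, and neuron and Schwann cell genes a median of -0.43 over 8. No member of either list passed on its own, while with the block 4 and 3 did, and 2 hypoxia genes were higher and 3 neuron genes lower when adjusted over the list alone. Members that passed with the block included Ndrg1 at 1.37 and the receptor tyrosine kinase Ret at -2.05 log2 units. Ret was detected on 1 dexamethasone array. Camera adjusted p was 0.011 and 0.012, and with an estimated correlation the adjusted p was 0.57 and 0.56. Without control replicate 1 the medians were 0.16 and -0.03, with adjusted p of 0.12 and 0.39. Without control replicate 2 they were 0.42 and -1.004, and the hypoxia median was 0.45 without dexamethasone replicate 1 and 0.05 (adjusted p = 0.20) without dexamethasone replicate 2. The neuron median was -0.17, -0.22 and -0.15 without background correction, with normexp and in the authors' processed values, -0.09 without the filter and -0.89 with the strict filter.

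Camera called none of the remaining lists at an adjusted p under 0.05, which does not show them to be unshifted. Among 22 fibroblast and extracellular matrix genes Lox, the collagen and elastin cross-linking enzyme, rose by 1.86 ± 0.25 log2 units (SE, adjusted p = 0.047). Eln, elastin, stood 1.30 ± 0.18 higher (adjusted p = 0.052; 0.016 with the block). The list's median was 0.03 (camera adjusted p = 0.28). Among 21 leukocyte genes F13a1, a coagulation factor subunit made by macrophages, rose by 2.52 and Ms4a7, a macrophage membrane protein gene, fell by 1.33 log2 units (adjusted p = 0.029 and 0.045), with a list median of -0.11 and a camera adjusted p of 0.15. Ptprc was not tested. In the steroid receptor and steroid metabolism list Hsd11b1 was the 1 member of 11 that rose (median -0.08, camera adjusted p = 0.71), and in the retinoid list it was Tgm2, transglutaminase 2, of 13 (1.25 log2 units, median -0.16, camera adjusted p = 0.26). No member passed among endothelial genes (median 0.04, camera adjusted p = 0.28), where Pecam1 stood 0.06 ± 0.14 higher, or among lipid-storing fibroblast (0.37, 0.056), pericyte (-0.02, 0.44), mesothelial (0.14, 0.31), red blood cell (0.21, 0.20), cartilage and heart (0.26, 0.21), interferon (-0.20, 0.15), sterol synthesis (-0.04, 0.77) and stress response genes (-0.08, 0.99), each given as median and camera adjusted p. With the block, 4 fibroblast genes and 4 endothelial genes were higher and 1 endothelial gene was lower. It called 1 leukocyte gene higher and 3 lower, 1 retinoid gene higher and 3 lower, 1 interferon gene higher and 3 lower, and 3 stress genes higher and 1 lower. Of the ciliated and neuroendocrine genes it called 2 higher and 2 lower, of the cartilage and heart genes 1 higher and 1 lower, and it called 2 mesothelial genes and 1 pericyte gene higher and 1 lipid-storing fibroblast gene lower. Adjusted over the list alone, without the block, 5 ciliated and neuroendocrine genes were higher and 4 lower, 4 fibroblast genes were higher and 1 lower, and 3 endothelial, 2 cartilage and heart, 1 mesothelial and 1 steroid metabolism genes were higher. For leukocyte genes the counts were 1 higher and 2 lower, for interferon genes 1 and 2, for retinoid genes 1 and 3, and for lipid-storing fibroblast genes 1 and 1, while 1 cartilage and heart gene was lower. No pericyte, red blood cell, sterol synthesis, stress or branching signal gene passed over its list alone.

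**Figure D2:**
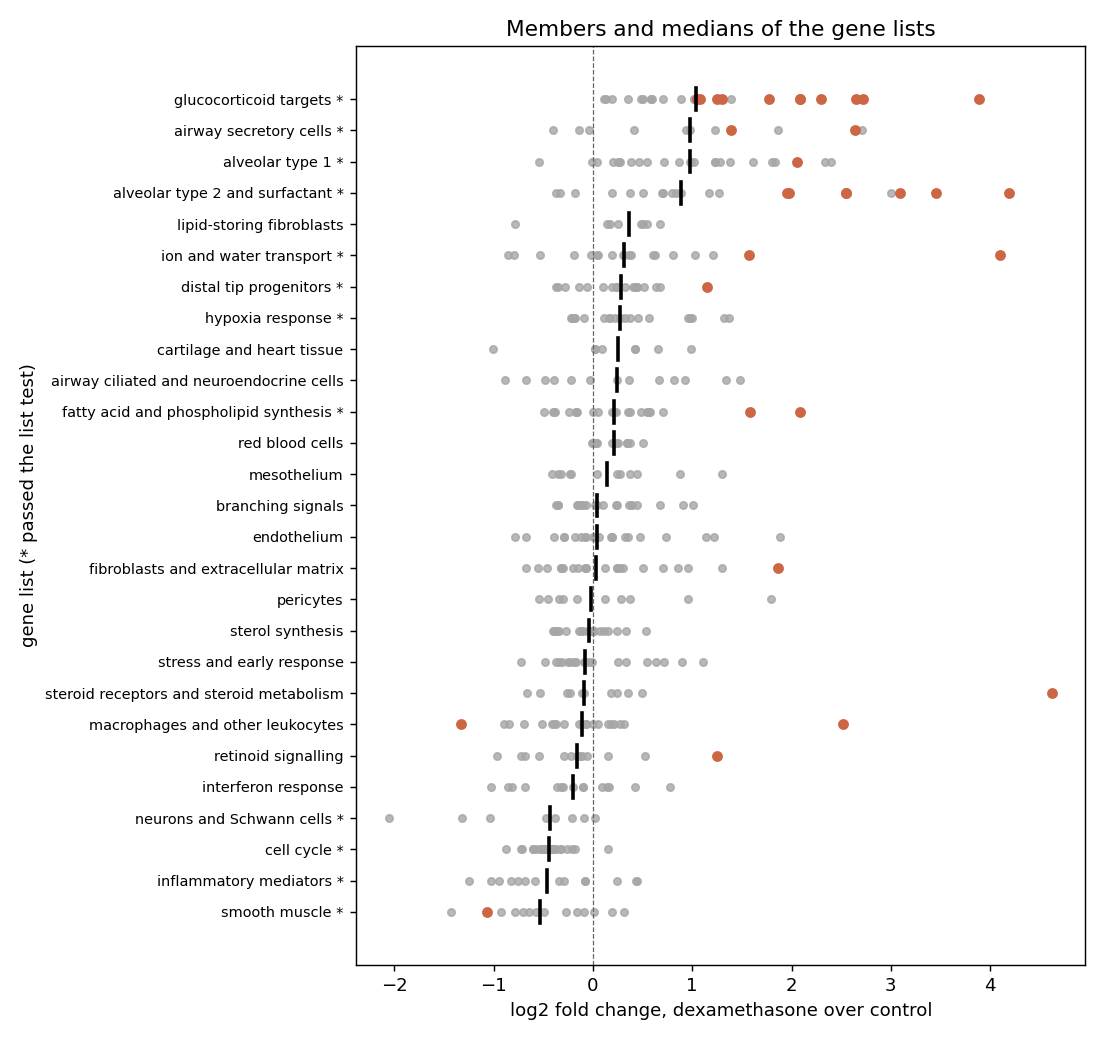
Log2 fold changes of the measured members of the 27 gene lists, dexamethasone over control, with genes that passed the test in orange, other genes in grey and a black bar at each list's median; an asterisk marks the 12 lists that camera called with the preset correlation. The medians run from -0.53 for smooth muscle to 1.04 for glucocorticoid targets.

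Differences were also taken within each experiment. Hsd11b1 stood 4.83 and 4.42 log2 units higher with dexamethasone in experiments 1 and 2, Sftpb 2.41 and 2.69, and Myl9 at -1.14 and -0.99. Across all 13714 genes, which are not independent replicates, the differences had a Pearson r of 0.66 and a Spearman rho of 0.53, and 68.3% of the genes had the same sign. In both experiments 223 genes were over 2-fold higher and 52 over 2-fold lower, and 1 gene moved over 2-fold in opposite directions. The 2 differences share no array. Array profiles correlated at 0.989 between the controls, at 0.988 between the dexamethasone arrays and at 0.965 to 0.979 between groups.

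**Figure D3:**
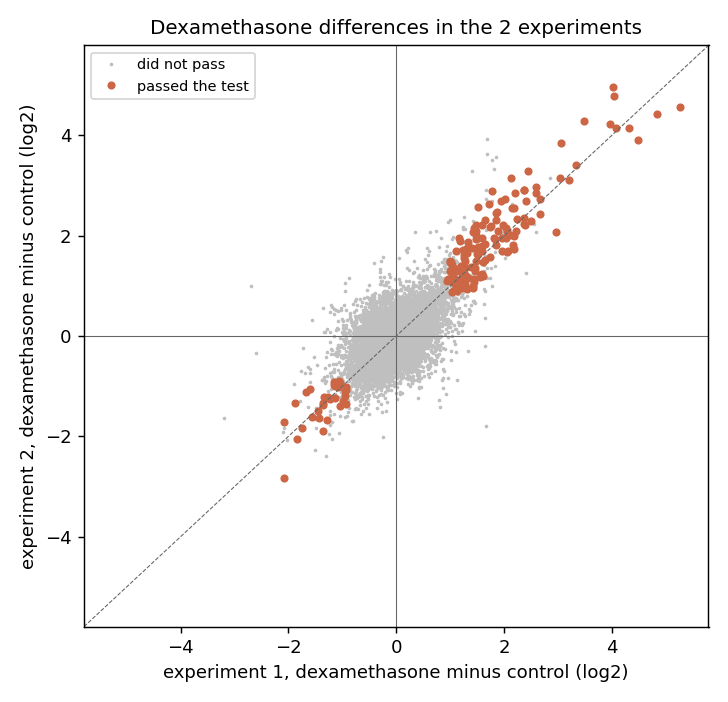
Difference between dexamethasone and control arrays on the log2 scale for each gene, experiment 1 on the horizontal and experiment 2 on the vertical axis, with genes that passed the test in orange and the line of equal difference dashed. Over all genes 68.3% have the same sign in both experiments.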

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

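All alternatives were set before the data were examined. The 171 changed genes became 666 under quantile normalization without background correction, 608 with normexp, 731 in the authors' processed values, 525 with a median shift, 826 with the replicate block and 867 with an intensity trend and robust variance, of which 165, 170, 165, 171, 171 and 170 were among the 171. The strict filter gave 308 genes (116 of the 171, with 10616 genes tested) and no filter 40 (all among them, with 28860 tested). Testing each probe gave 180, the mean of a gene's probes 164, a fold of at least 1.5 gave 171, adjusted p under 0.10 gave 592 and unadjusted p under 0.05 gave 2667. Leaving out 1 array gave 8 to 95 genes, with 1 residual degree of freedom. The cause of the other shifts was not tested.

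Camera called 12 to 14 lists under every alternative in normalization, filter, block and variance and with the mean of a gene's probes, against 12. Lists were not tested with each probe on its own. With an estimated correlation it called 0, fry called 2 (smooth muscle, fatty acid and phospholipid synthesis) and fry with the replicate block 3 (inflammatory mediators as well). Fry asks whether a list's genes move one way on balance, without comparing them with other genes. The replicate block changed no list's camera call. Lipid-storing fibroblast genes passed under 7 alternatives with all 4 arrays, for example at an adjusted p of 0.038 in the authors' processed values, and red blood cell genes passed without a filter (0.043). On leaving out 1 array, red blood cell genes passed without control replicate 1 (0.021), lipid-storing fibroblast genes without dexamethasone replicate 1 (0.013), and mesothelial (0.021) and interferon genes (0.043) without dexamethasone replicate 2. Of the named genes, 39 passed: the block kept all 39 and added 56, 23 lost their call without a filter, and 33, 33, 19 and 33 lost it without control replicate 1, control replicate 2, dexamethasone replicate 1 and dexamethasone replicate 2.

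The Pearson r of the 2 experiments' differences, 0.66, was 0.74 without background correction, 0.72 with normexp, 0.75 in the authors' processed values, 0.72 with the strict filter and 0.56 without a filter.

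No list and none of the 39 named genes that passed changed sign under an alternative that gave it a value, and the strict filter gave one to 23 of the 39. Among those that did not pass, the authors' processed values turned the medians of pericyte (0.029), leukocyte (0.0010), sterol synthesis (0.024), steroid receptor (0.0048) and stress genes (0.016), and Aqp5 (-0.00089). The strict filter turned ciliated and neuroendocrine (-0.22) and steroid receptor genes (0.051); the ciliated and neuroendocrine median, 0.25, was 0.036 without a filter and 0.038 to 0.44 on leaving out 1 array. Leaving out 1 array gave medians of -0.072 to 0.13 for fibroblast, -0.020 to 0.12 for endothelial, 0.0048 to 0.15 for pericyte, -0.29 to 0.12 for sterol synthesis, -0.10 to 0.24 for mesothelial and -0.33 to 0.052 for stress genes, and, without a turn, -0.21 to -0.17 for leukocyte, 0.046 to 0.12 for branching signal, -0.20 to -0.078 for interferon, 0.099 to 0.32 for red blood cell, -0.10 to -0.033 for steroid receptor, 0.13 to 0.30 for cartilage and heart, -0.26 to -0.096 for retinoid and 0.23 to 0.50 for lipid-storing fibroblast genes. It gave -0.039 to 0.42 for Car2, -0.29 to 0.38 for Aqp5, -0.73 to 0.46 for Sox2, -0.030 to 0.15 for Pecam1 and -0.27 to 0.96 for Hbb-y, and, without a turn, 0.74 to 1.82 for Ager, 0.45 to 1.14 for Sftpc, 0.24 to 0.70 for Pdpn, 0.14 to 0.75 for Id2, 0.25 to 0.59 for Etv5, 0.042 to 0.43 for Shh, 0.038 to 0.45 for Foxj1 and 0.084 to 0.30 for Sox9. Other normalizations and filters also moved medians of lists that did not pass by over 1.5 times, for example that of cartilage and heart genes from 0.26 to 0.031 without a filter. Signal near background limits the dim genes: neqc brings the lowest detected signal to at most 5.06 on the log2 scale, and 21 of the 171 genes were not detected on either control array.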

Other observations

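The tests of process terms and those of the leukocyte and smooth muscle genes were chosen only after the data had been seen. The general epithelial list was drawn up after other results but before its own values were seen. In the process terms of the array's annotation (377 terms of 10 to 300 tested genes), camera with the preset correlation called 7 terms higher and 11 lower with dexamethasone, and none with an estimated correlation (adjusted p = 0.96 for each). As for the lists, the setting with an estimated correlation had little power. Among the higher terms, sodium ion transport was higher (median 0.20 over 45 genes, adjusted p = 0.029), with Scnn1a, Slc34a2 and Slc10a6 among the members that rose. Lipid transport was higher (median 0.23 over 39 genes, adjusted p = 0.012), with Apoc1, Lbp and Osbpl6 rising by 1.65, 1.42 and 1.05 log2 units. Glutathione metabolism had a median of 0.34 over 15 genes (adjusted p = 0.011) with no member that passed.

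The 11 lower terms included DNA replication (median -0.30 over 90 genes, adjusted p = 0.0030), nucleosome assembly (-0.30 over 69, adjusted p = 0.0030), RNA splicing (-0.18 over 150, adjusted p = 0.0043) and ribosomal RNA processing (-0.17 over 48, adjusted p = 0.036), and beside them messenger RNA processing, cell division, mitosis, DNA repair, the DNA damage response, DNA recombination and ribosome biogenesis, none with a member that passed. Further genes, chosen after their values were seen, were Cela1, a pancreatic-type elastase, which rose by 3.38, the epidermal growth factor family ligand Areg by 2.64 and the cell cycle inhibitor Cdkn2b by 2.37 log2 units. Cdkn2b was detected on 1 control array. Angpt1, a ligand of the endothelial receptor Tek, fell by 1.05 (adjusted p = 0.041). The array also carries a probe for eGFP, which is no mouse gene, and the sources used here do not say whether the embryos carried a reporter or whether the probe binds another transcript. It stood at 9.02 in control and 6.61 with dexamethasone, with differences of -3.19 and -1.64 in the experiments (adjusted p = 0.082, and 0.027 with the replicate block).

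The alveolar type 2 list had a median of 0.89 (95% bootstrap interval over members 0.70 to 1.98). This and the other bootstrap intervals below resample members as if independent, with the 4 arrays held fixed. They leave out the spread between arrays. A larger share of epithelial cells would raise genes of epithelium in general alike, but 22 such genes, none of them in the type 2 list and 2 (Krt8 and Krt18) in the mesothelial list, had a median of 0.36 (0.18 to 0.44), and the lowest median of the type 2 list under the 4 other normalizations was 0.79. A larger epithelial share may still account for part of this shift, since the general epithelial median lay above 0. How large a part cannot be told, since the intervals leave out the spread between arrays. These tests leave at least 2 hypotheses. They are a response of type 2 genes within the cells and a larger share, within the epithelium, of cells that express them. Whether type 2 cells were present in these explants of embryonic day 14 was not measured. Measuring these genes cell by cell in such explants could separate the hypotheses. The rise was not particular to type 2 genes. The medians were 0.97 for alveolar type 1 and 0.98 for airway secretory genes (0.92 and 0.27 without the detection filter). A cause shared by these lists was not tested.

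Among leukocyte genes F13a1 rose by 2.52 (95% interval 1.89 to 3.14) and Ms4a7 fell by 1.33 (-1.76 to -0.90). The intervals of these genes are of the fit over arrays, unlike the bootstrap intervals over members. Both genes were picked because they passed, after the list's values were seen. The comparisons that follow therefore describe the list and are no independent tests. A larger share of leukocytes would raise the other members as much as F13a1, yet the bootstrap interval of their median reached up to 0.031. A smaller share as the whole cause would lower them as much as Ms4a7, yet the interval of the median without Ms4a7 reached down to -0.38. It may still account for part of that fall, since only 8 of the list's 21 members had positive values. Aif1 and Cd52 stood at -0.89 and -0.69 without passing, and Cd52 passed with the replicate block (adjusted p = 0.15 and 0.044). F13a1 and Ms4a7 were the only members of the list that passed without the block, and with it 1 member was higher and 3 were lower. What sets F13a1 and Ms4a7 apart from the others was not tested.

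The smooth muscle list had a median of -0.53 (95% bootstrap interval -0.78 to -0.09). If the mesenchyme as a whole had a smaller share, the fibroblast and extracellular matrix list would be lower as well. Its median was 0.03, but its interval, -0.20 to 0.29, overlapped that of smooth muscle, so a smaller mesenchymal share cannot be told apart from a change in smooth muscle genes with these members. Normalization may set part of the size, since the median was -0.27 in the authors' processed values and the wide interval leaves this open.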
